A study of Mus musculus with 3 samples.

How the data were processed

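The 3 libraries hold droplet single-cell RNA profiles of immune cells sorted from mouse lung. They cover 3 genotypes with 1 library each, per the labels: wild type, Axl knockout, and Zbtb46-Cre crossed to floxed Axl, in which Cre is expressed under the control of the dendritic cell transcription factor gene Zbtb46. Cells of one genotype were tagged with sample barcodes, pooled and run in one lane, per the labels' protocols. The tag counts were not used here, so animals within a lane could not be told apart, and the number of animals is not given in the sources used here. The labels also give KP as the cell line. How and when such cells were given is not stated in the sources used here.

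Each library is a raw matrix of unique molecular identifier (UMI) counts as deposited, with 6794880 barcodes and 31053 genes listed, and no normalisation. The counts were made with Cell Ranger, version 3.1.0 per the file headers and version 2.1 per the submitters' processing notes, against mm10. The labels' protocol and the series design text name different kits (3' and 5'), numbers of cells per lane and sequencers, so which of them made these libraries is left open. The annotation release behind the counts is not given in the sources used here. The series design text states a filter of more than 500 UMIs and at most 25% mitochondrial UMIs per barcode, 15 principal components, Seurat clustering with a batch correction, and removal of doublets by sample tags where applicable. No cell annotation was used here.

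The stated filter was applied to the deposited counts. It left 6279 barcodes of the Zbtb46-Cre Axl-flox library, 7211 of the Axl knockout library and 6748 of the wild type library, after removal of 600, 791 and 595 barcodes with a high mitochondrial share. Scrublet, as run in Scanpy 1.11.5, marked 0, 1 and 0 barcodes as doublets. At 0%, 0.0139% and 0% of barcodes, below the 0.5% taken here as the least a working caller marks, doublet removal did not work, and doublets remain among the cells. The marked cell was removed, clusters joining markers of macrophages with those of cDC1 or mature dendritic cells were kept out of every class (the rule did not cover cDC2 markers), and removal of the highest 6% of Scrublet scores was added as an alternative.

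Counts were scaled to 10000 per cell and log transformed, and 2000 variable genes among those seen in at least 10 cells gave 15 components, a graph of 15 neighbours and Leiden clusters at resolution 1 with random seed 1, on the merged libraries without batch correction. Clusters of dendritic cells were clustered again on their own (anndata 0.12.19, python-igraph 0.11.9, numpy 2.4.6). Of 23 marker lists, those with more markers detected than not, and at least 3 detected, were used for scoring. The lists of alveolar macrophages (4 of 10 markers detected) and non-classical monocytes (4 of 8) were among those not scored. Each cluster took the name of the highest score with "-like" added. A marker counted as detected at a mean of at least 0.25, and leading genes had to be seen in at least 20% of a cluster's cells. A cluster stayed unnamed in 3 cases. The first is scores of at least 0.35 for both macrophages and cDC1 or mature dendritic cells (mixed clusters). The second is a pair of dendritic cell scores within 0.1 of each other, or more markers of another class among its 10 leading genes (clusters between classes). The third is few UMIs with no marker of the class among the 10 leading genes (shallow clusters). These scoring rules and thresholds were set and revised after the clusters had been seen, since under the first rules the addition of 1 cell moved cells between the mature and cDC2-like classes.

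Counts were summed over the cells of each class and library and expressed as counts per 1000000 UMIs of that sum (CPM). With 1 library per genotype no test between genotypes was possible, so no p-value, standard error or number of changed genes is given, and no difference has a replicate check. Levels carry exact Poisson intervals, ratios the interval that follows from them, and shares of cells above 0 exact binomial (Clopper-Pearson) intervals, all at 95%; a share of 0 is given with the limit of 3 cells of the total. These intervals cover counting error only. They do not cover differences between animals, sorts, lanes or cluster assignments. A class was compared where each library held at least 30 cells, which left 6 classes. With 18 pathway lists, the median log2 ratio of CPM + 10 was taken over members with at least 20 counts in the pair of libraries; its interval came from 2000 Poisson redraws of the counts, and its percentile from 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these libraries and is no test. Lists with fewer than 3 measured members gave no median. The lists leading the text are those of cholesterol synthesis, cholesterol efflux, immunogenic maturation, immunoregulation and the type I interferon response, in the mature class.

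Genes were named by a fixed rule: those with the highest and lowest log2 ratio of CPM + 10 among genes with at least 50 counts in the pair and at least 50 CPM in one library. The rule took 10 per side in the mature class against wild type, 5 per side in the other comparisons of dendritic cells and 3 per side in other classes. Mitochondrial and ribosomal protein genes, Gm and Rik gene models, receptor segments, haemoglobins, Xist, Tsix and Y-linked genes were left out. Axl, Mertk and list members named with their list were added. Ratios printed for single genes are of CPM without the added 10. Genes whose share of free RNA (barcodes with 10 to 100 UMIs) was at least 0.5 times their share in the class were to be named as such. In the dendritic cell and macrophage-like classes this held for most genes the rule named, so there the exceptions are named instead. The filters, lists, markers, naming rule and the alternatives not described as added were fixed before the data were examined. Single values of some list members are not reported here; list medians include them.

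The calculations (Python 3.11.15, pandas 2.3.3, scipy 1.17.1) were tested on simulated counts for the Axl knockout against wild type, with 200 genes changed by known folds. The counts were Poisson draws at wild type rates, the model behind the intervals. Coverage near 95% follows from that model, so it checks the calculation and not differences between cells or animals. In the mature class (6670 genes) the ratio intervals covered the true value for 95.5% of genes. The 10 highest genes were all changed ones, and the 10 lowest were not checked. A list of 14 genes raised 1.5-fold gave a median log2 ratio of CPM + 10 of 0.55 at percentile 100, and 4% of 200 unchanged lists fell outside the central 95%. Such lists gave 0.52 in the cDC1-like class (9107 genes) and 0.49 in the cDC2-like class (10626 genes). Alternatives were a minimum of 1000 UMIs, a maximum of 10% mitochondrial UMIs, Scrublet calls kept, Leiden resolution 1.5 with 30 components, classes from each cell's own highest score, cells weighted equally, scaling by TMM factors (edgeR 4.0.16 in R 4.3.3), subtraction of free RNA at 10% of a class's counts (more than the 1.09% to 2.53% of its free RNA level at which the macrophage gene Gpnmb stood in the dendritic cell classes, so it removes too much there), a minimum of 100 counts or none for list members, and a pseudocount of 1 CPM. Added after the data were seen were the removal of the highest 6% of Scrublet scores, the joining of the clusters between classes to the cDC2-like class, cluster profiles weighted as in the wild type library, and list medians without the added 10 CPM. Positions of genes are from GENCODE vM21 on mm10.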

Results

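Immune cells from the lungs of mice of 3 genotypes were profiled by droplet single-cell RNA sequencing, with 1 library each for wild type, Axl knockout and Zbtb46-Cre Axl-flox. Axl is a receptor tyrosine kinase of the TAM family (Tyro3, Axl, Mertk) that mediates the uptake of dying cells, and Zbtb46 marks conventional dendritic cells. The series title names cholesterol mobilisation, dendritic cell maturation and the immune response to cancer, so the comparisons ask which dendritic cell genes differed when Axl was lost everywhere or where Zbtb46-Cre acts. The libraries held 63960820 UMIs (Zbtb46-Cre Axl-flox), 59268081 UMIs (Axl knockout) and 65020290 UMIs (wild type). The cells kept numbered 6279, 7210 and 6748, with medians of 8709, 7119 and 8136 UMIs and 2541, 2125 and 2358.5 genes per cell. Counts were found for 18504, 18597 and 18492 genes, and 93.2%, 93.6% and 93.7% of all UMIs lay in kept cells. Intervals in brackets are 95% counting intervals.

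In the dendritic cell and macrophage-like classes, Axl transcripts were far lower in the Axl knockout library and moderately lower in the Zbtb46-Cre Axl-flox library than in wild type. Among these classes Axl in wild type stood highest in macrophage-like cells, at 245 CPM [239, 251], followed by cDC2-like cells at 117 [111, 123], cDC1-like cells at 46.2 [40.8, 52.2] and mature dendritic cell-like cells at 33.6 [27.0, 41.5]. The Axl knockout library gave 29.1 [24.8, 33.8], 7.82 [6.80, 8.94], 3.73 [2.52, 5.33] and 2.80 [1.28, 5.31] CPM in the same order. These are log2 ratios to wild type of -3.07 [-3.30, -2.85] in macrophage-like, -3.90 [-4.12, -3.70] in cDC2-like, -3.63 [-4.23, -3.08] in cDC1-like and -3.59 [-4.76, -2.60] in mature cells. In the Zbtb46-Cre Axl-flox library the log2 ratio to wild type was -1.17 [-1.30, -1.04] in cDC2-like cells, -0.71 [-1.06, -0.37] in cDC1-like cells and -0.70 [-1.32, -0.12] in mature cells. It was -0.69 [-0.74, -0.63] in macrophage-like cells, a population in which Zbtb46 is not the usual marker. Axl (ENSMUSG00000002602) lies on the minus strand of chromosome 7, at 25757273 to 25788705 in mm10. Which exons are deleted is not given in the labels, and a sequenced tag outside the deleted part would check nothing, so these levels check the genotypes only if the tags fall inside it. Mertk (ENSMUSG00000014361, chromosome 2, plus strand, 128698956 to 128802894), the other TAM receptor seen, stood in macrophage-like cells at 93.9 CPM [90.3, 97.6] in wild type, 88.9 [81.4, 97.0] in Axl knockout and 85.0 [81.7, 88.3] in Zbtb46-Cre Axl-flox. Tyro3 had at most 2 counts in any class.

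**Figure D1:**
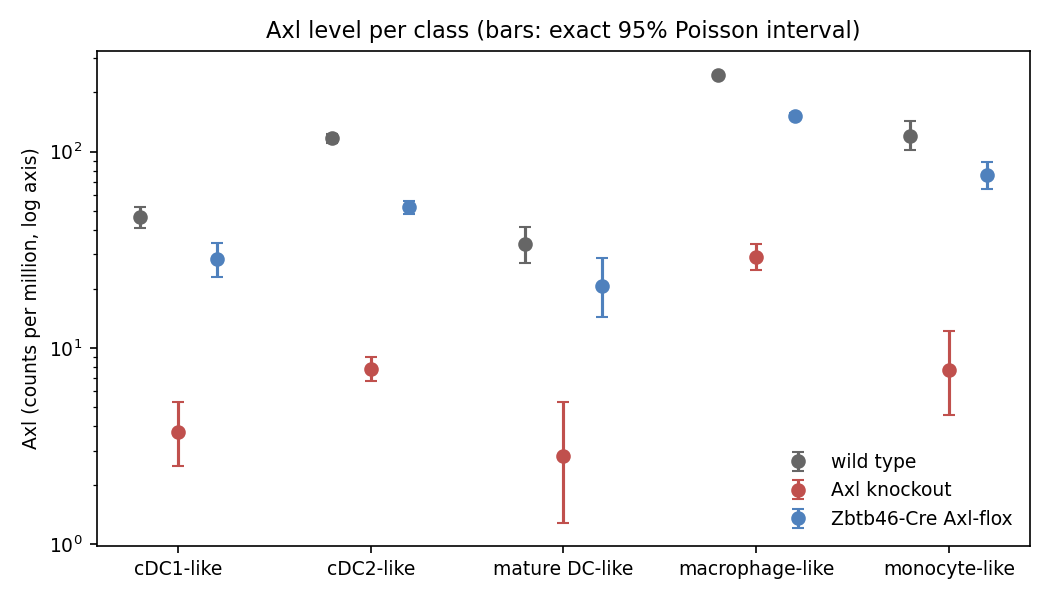
Axl level in CPM (vertical log axis) per class (horizontal axis) in the 3 libraries; points are single libraries and bars are exact 95% Poisson intervals. In macrophage-like cells the points lie at 245 (wild type), 152 (Zbtb46-Cre Axl-flox) and 29.1 (Axl knockout), and in cDC2-like cells at 117, 52.1 and 7.82.

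The Axl knockout library held few macrophage-like cells and many cDC2-like cells. Macrophage-like cells, phagocytes marked by C1q and Apoe, made up 8.70% of its cells [8.06, 9.37], against 39.8% [38.6, 41.0] in wild type and 46.1% [44.8, 47.3] in Zbtb46-Cre Axl-flox. The cDC2-like class, dendritic cells that mainly prime CD4 T cells, held 50.9% [49.7, 52.0], 25.4% [24.4, 26.5] and 26.7% [25.6, 27.8] in that order. The cDC1-like class, which cross-presents antigen to CD8 T cells, held 12.5% [11.7, 13.3], 9.32% [8.64, 10.04] and 6.10% [5.52, 6.72]. Mature cells, dendritic cells expressing the lymph node homing receptor Ccr7, held 7.70% [7.09, 8.34], 6.14% [5.57, 6.73] and 4.48% [3.98, 5.02]. Among cells of the 3 dendritic cell classes alone, however, the mature share was highest in wild type, at 15.0% [13.7, 16.4] of 2758 cells, against 10.8% [10.0, 11.7] of 5122 in Axl knockout and 12.01% [10.7, 13.4] of 2339 in Zbtb46-Cre Axl-flox. The cDC1-like share of the same cells was 22.8% [21.3, 24.4] in wild type, 17.6% [16.5, 18.6] in Axl knockout and 16.4% [14.9, 17.9] in Zbtb46-Cre Axl-flox, and the cDC2-like share 62.2% [60.3, 64.0], 71.6% [70.3, 72.8] and 71.6% [69.7, 73.4] in that order. Immune cells were sorted, so every share carries the sort, whose gate is not given. Clusters kept out of the classes held, in the order Zbtb46-Cre Axl-flox, Axl knockout, wild type, 4.57%, 6.50% and 6.18% of cells (between classes), 4.81%, 4.15% and 6.99% (macrophage mixed with cDC1 or mature dendritic cell genes) and 3.90%, 4.36% and 4.02% (shallow).

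**Figure D2:**
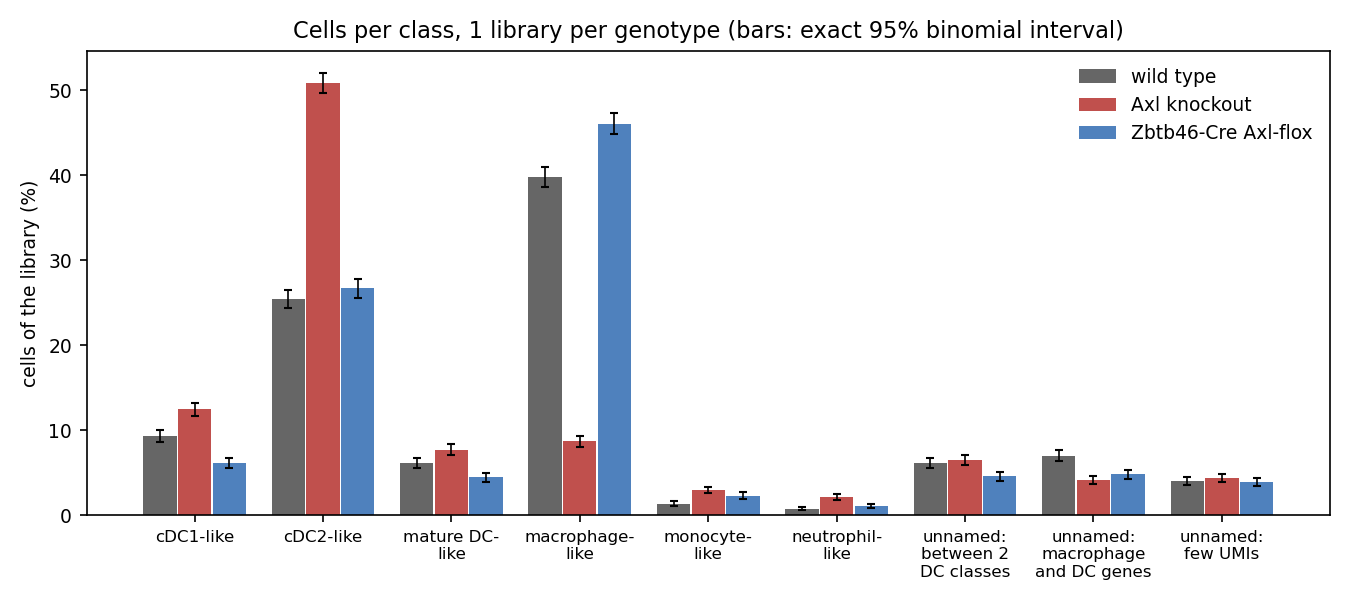
Percent of each library's cells (vertical axis, from 0) per class (horizontal axis) in the 3 libraries, with exact 95% binomial intervals as bars. Macrophage-like cells stand at 46.1%, 8.70% and 39.8% and cDC2-like cells at 26.7%, 50.9% and 25.4% in Zbtb46-Cre Axl-flox, Axl knockout and wild type.

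In mature cells of the Axl knockout library, Cd80 and the median of NF-kB genes were higher than in wild type. The medians of interferon and MHC class II genes were lower. However, the NF-kB median was 0 with free RNA subtracted, and the MHC class II median was close to 0 under some alternatives. Cd80, the costimulatory ligand of CD28, stood at 126 CPM against 61.9, a log2 ratio of 1.03 [0.76, 1.30]. Isg15, a ubiquitin-like protein made in response to interferon, stood at 45.1 against 87.4 CPM (-0.95 [-1.27, -0.65]). Cd74, the MHC class II chaperone, stood at 5778 against 7726 CPM (-0.42 [-0.45, -0.39]). Cholesterol synthesis genes, whose transcription SREBP2 drives, showed no shared direction.

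All genes of this comparison had a median log2 ratio of 0.06, and TMM scaling moved ratios by -0.10. The immunogenic maturation list had a median log2 ratio of 0.25 [0.01, 0.36], 0.19 relative to all genes, at percentile 99.9, with 8 members higher and 5 lower. Besides Cd80 it held Cd86 (0.35 [0.16, 0.55]) and Il15ra, which presents IL-15 to T cells (0.70 [0.47, 0.93]), while Il12b, a subunit of IL-12, was lower at 127 against 178 CPM (-0.48 [-0.68, -0.29]). Il12b was also a leading gene of the smaller mature cluster, which held 20.6%, 16.9% and 12.8% of the class in Zbtb46-Cre Axl-flox, Axl knockout and wild type. Over members with at least 100 counts this median was 0.09. Immunoregulatory genes had a median of 0.11 [-0.00, 0.22], 0.05 relative and 0.02 under TMM scaling, with 7 higher and 3 lower. Of the pair of PD-1 ligands, Cd274 gave 0.09 [-0.07, 0.25] and Pdcd1lg2 -0.56 [-0.82, -0.29]. The sign of the immunoregulation median turned to -0.05 when classes came from each cell's own score. Cholesterol synthesis and uptake gave 0.05 [-0.06, 0.15], -0.01 relative, at percentile 39.5, with 12 members higher and 9 lower, and -0.03 with the 1 Scrublet call kept. Cyp51, a demethylase of the pathway, was at 0.80 [0.50, 1.10] and Fdft1, squalene synthase, at -0.55 [-1.12, 0.01]. The list of cholesterol efflux, storage and lysosomal export gave -0.07 [-0.20, 0.06], -0.13 relative, with 7 higher and 9 lower, and 0.05 with the Scrublet call kept. Apoe, the lipid carrier, was at 161 against 210.4 CPM (-0.38 [-0.56, -0.21]). In free RNA, however, Apoe stood at 1609 CPM in Axl knockout and 9758.5 in wild type. The class held 10.0% and 2.16% of these levels, so the lower Apoe need not lie in the mature cells themselves. Beside this list, markers of macrophages had a median of -0.32 [-0.44, -0.15] in the same cells, 0 higher and 10 lower.

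The interferon list had a median of -0.18 [-0.33, -0.06], -0.24 relative to all genes, at percentile 0.01, 5 members higher and 11 lower. Cxcl9, a chemokine that attracts T cells, stood at 5.60 against 35.2 CPM (-2.65 [-3.47, -1.91]), while Ifit2 was at 1.07 [0.11, 2.12]. MHC class II genes gave -0.34 [-0.38, -0.17], -0.40 relative, with 1 higher and 10 lower. This value was -0.03 with classes from each cell's own score and -0.06 with the 1 Scrublet call kept. NF-kB and inflammatory cytokine genes gave 0.41 [0.21, 0.53] (0.35 relative; 10 higher, 3 lower), with Tnfaip3, an inhibitor of NF-kB signalling, at 0.62 [0.35, 0.90] and Nfkbia at 0.52 [0.39, 0.65]. This median was 0.00 after subtraction of free RNA, which left 3 of the 13 members at 0 in both libraries, and 0.18 with the Scrublet call kept. Migration genes gave -0.07 [-0.13, -0.03], -0.13 relative, and the IL-4 response -0.11 [-0.15, 0.02], -0.17 relative.

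By the naming rule the genes highest in mature cells of the Axl knockout library were Zfp36l2, which promotes mRNA decay (1.89), Plet1, a surface protein of lung dendritic cells (1.37), the transcription factors Runx1 (1.31), Fos (1.05) and Tcf4 (0.99), Txnip (1.08), Man2a1 (1.04), Cd80 (1.03), Pdcd4 (1.02) and the signalling adaptor Traf6 (1.00). Lowest were Ifi27l2a, an interferon-induced gene (-2.16), the lysozyme Lyz2 at 62.8 against 199 CPM, Slfn5 (-1.01), Usmg5 (-0.98), Isg15 (-0.95), the galectins Lgals3 (-0.94) and Lgals1 (-0.83), the lysosomal enzymes Hexa (-0.78) and Ctsd (-0.76), and the hyaluronan receptor Cd44 (-0.77). Free RNA held these genes at 0.5 times their share in the class or more, except Cd80, Traf6 and Isg15. Lyz2 in free RNA stood at 1297 CPM in Axl knockout and 8732 in wild type, so its lower level need not lie in the mature cells themselves.

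In mature cells of the Zbtb46-Cre Axl-flox library, the cholesterol synthesis median, the chemokines Ccl17 and Ccl22, Cd80 and PD-L1 were higher than in wild type. Hmgcs1, an early enzyme of the synthesis pathway, stood at 114 against 54.1 CPM (log2 ratio 1.08 [0.75, 1.40]). Idi1, the isoprenoid isomerase, stood at 248 against 155 CPM (0.68 [0.48, 0.88]). Ccl17 and Ccl22, ligands of CCR4, stood at 2697 against 1892 (0.51 [0.45, 0.57]) and 1835 against 1252 CPM (0.55 [0.48, 0.62]). Cd80 was at 139.7 against 61.9 CPM (1.18 [0.88, 1.48]) and Cd274, encoding PD-L1, at 282 against 208 (0.44 [0.26, 0.62]).

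All genes of this comparison had a median log2 ratio of 0.11, and TMM scaling moved ratios by -0.15, so list medians are given with the value relative to all genes. Cholesterol synthesis and uptake gave 0.25 [0.13, 0.43], or 0.14 relative to all genes, at percentile 97.9 with 15 members higher and 7 lower. It was 0.16 under TMM scaling and 0.61 over members with at least 100 counts. Besides Hmgcs1 and Idi1, Msmo1 (1.30 [0.81, 1.80]) and the regulator Srebf2 itself (0.67 [0.38, 0.97]) were higher, and Sqle, squalene epoxidase, was at -0.11 [-0.63, 0.40]. Efflux, storage and export genes gave 0.12 [0.02, 0.37], 0.01 relative to all genes, with 11 higher and 4 lower. Among the members was Npc1, which exports cholesterol from lysosomes (0.91 [0.35, 1.49]). The list also held enzymes outside these functions: the desaturase Scd2 (1.21 [0.74, 1.70]) and Ch25h, which makes 25-hydroxycholesterol (1.65 [0.49, 2.91], from 20 and 10 counts). Apoe was at -0.14 [-0.35, 0.06].

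Immunogenic maturation genes gave 0.21 [0.08, 0.37], 0.10 relative to all genes, with 10 higher and 3 lower, and 0.08 with clusters weighted as in wild type. Cd40, which receives T cell help, was at 0.40 [0.13, 0.67], Cd86 at 0.42 [0.20, 0.64] and Il12b at 0.17 [-0.04, 0.38]. Immunoregulatory genes gave 0.21 [0.13, 0.39], 0.10 relative, with 10 of 10 members higher and 0 lower, and 0.09 under TMM scaling. Pvr, a ligand of TIGIT, was at 0.88 [0.48, 1.28] and Tgfb1 at 0.74 [0.33, 1.15]. Interferon genes gave -0.02 [-0.18, 0.17], -0.13 relative, with 7 higher and 7 lower. Isg15 was higher (0.63 [0.36, 0.91]) and Mx1, which blocks viruses, lower (-0.63 [-1.04, -0.23]). The IL-4 response list gave 0.31 [0.20, 0.51], 0.20 relative, with 9 of 9 higher, among them the cytokine-induced inhibitor Cish (1.10 [0.67, 1.53]). Its members Ccl22 and Il4i1 also served as markers of the mature class. NF-kB genes gave 0.27 [0.21, 0.47], 0.16 relative. MHC class II genes gave -0.20 [-0.25, -0.10], -0.31 relative, with 3 higher and 8 lower, and -0.02 at a minimum of 1000 UMIs.

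The genes highest by the rule were Olfr920 (1.41), Tcf4 (1.36), Msmo1 (1.30), Lars2 (1.23), Btla, an inhibitory receptor (1.23), Scd2 (1.21), Cd80 (1.18), Rufy3 (1.09), Hmgcs1 (1.08) and Mir155hg, the host of miR-155. Lars2 was also a leading gene of a shallow cluster kept out of the classes. Lowest were Tnni2, a troponin (-1.73), Ifi27l2a (-1.15), Zfp524 (-1.14), Lst1 (-1.10), Ggh (-1.07), H2-M2 (-0.95), the iron regulator Hfe (-0.92), Tmem176a (-0.84), Arhgdib (-0.80) and Sec61g (-0.77). Free RNA held less than 0.5 times the class share of Olfr920, Cd80, Rufy3, Mir155hg, Zfp524, H2-M2 and Tmem176a.

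Between the deletions, mature cells of Zbtb46-Cre Axl-flox had higher medians of IL-4 response, interferon and lipid handling genes than those of Axl knockout. The IL-4 response list gave a median of 0.44 [0.29, 0.56] (8 higher, 1 lower), with Ccl17 at 0.64 [0.59, 0.70]. Interferon genes gave 0.25 [0.03, 0.36] (11 higher, 5 lower), led by Isg15 at 135.5 against 45.1 CPM (1.59 [1.28, 1.90]). Efflux, storage and export genes gave 0.24 [0.14, 0.39] (14 higher, 1 lower) and cholesterol synthesis 0.18 [0.07, 0.34] (15 higher, 7 lower), with Hmgcs1 at 0.95 [0.65, 1.25]; lipid-associated macrophage genes gave 0.35 [0.21, 0.49] (10 higher, 1 lower). With free RNA subtracted, which removes too much here, the lipid-associated median was 0, with 4 of 11 members at 0 in both libraries. In free RNA the macrophage gene Gpnmb stood at 818 CPM in Zbtb46-Cre Axl-flox and 227 in Axl knockout. Immunoregulatory genes gave 0.26, with Pdcd1lg2 at 0.74 [0.46, 1.03], and Il12b stood at 199.9 against 127 CPM (0.65 [0.44, 0.87]), whereas Cd80 was at 0.15 [-0.09, 0.38]. By the rule Isg15, Mmp14 (1.20), Lars2 (1.19), Lyz2 (1.13) and Lilr4b (1.07) were highest and Zfp36l2 (-0.91), Fam53b (-0.90), Ppp1r15a (-0.89), H2-M2 (-0.85) and Pdcd4 (-0.81) lowest. Lyz2 turned to -0.09, with 10 CPM added, among cells with at most 10% mitochondrial UMIs. Free RNA held less than 0.5 times the class share of Isg15, Fam53b and H2-M2.

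**Figure D3:**
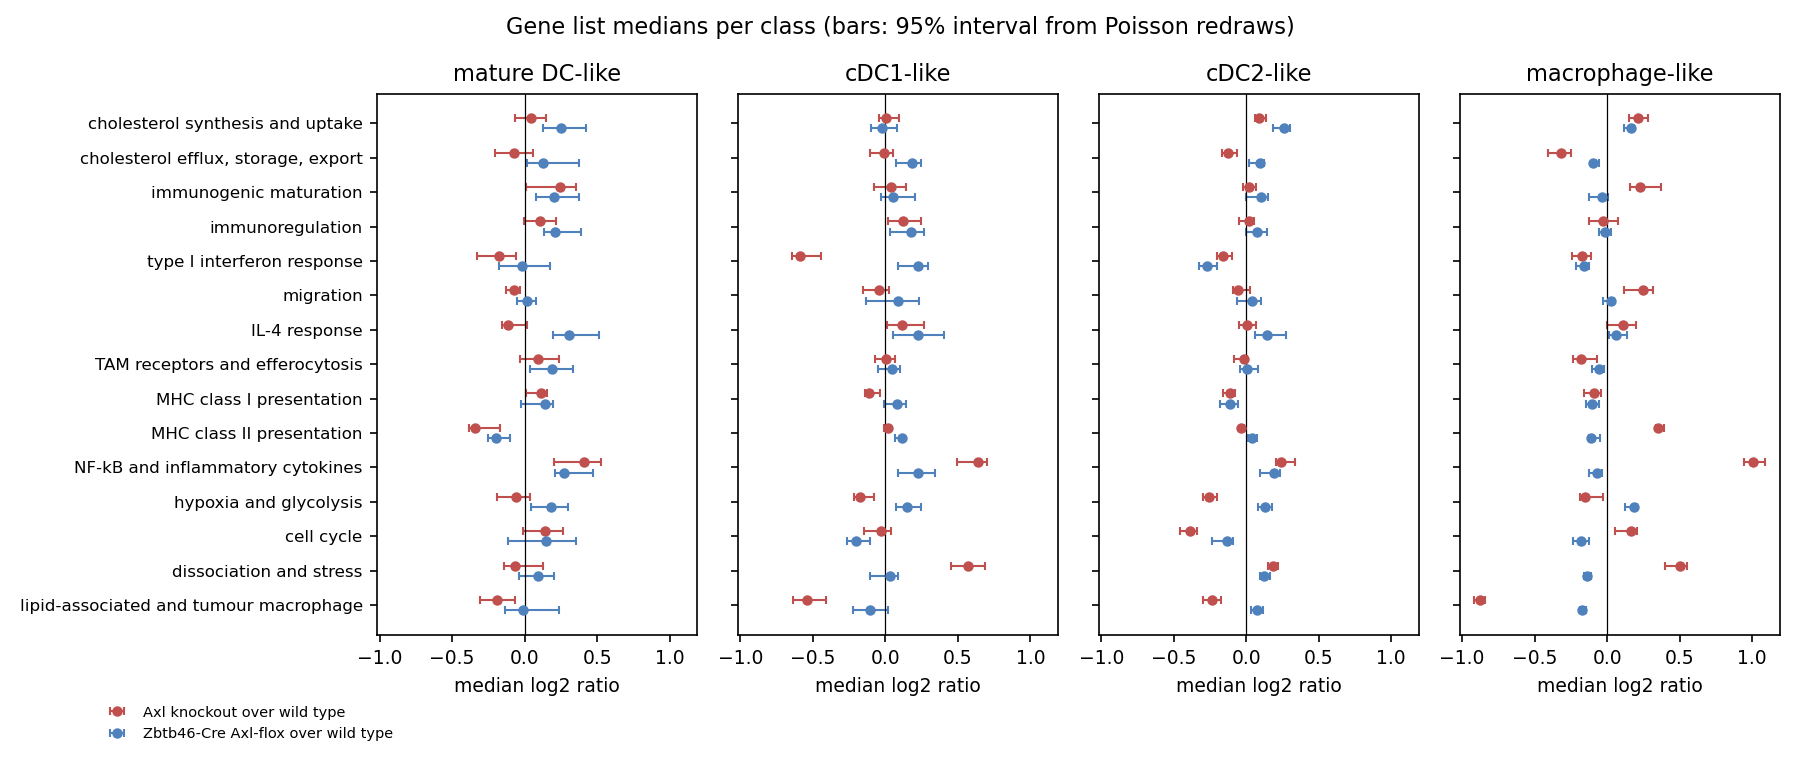
Median log2 ratio (horizontal axis) of gene lists (vertical axis) in 4 classes, for Axl knockout (red) and Zbtb46-Cre Axl-flox (blue) over wild type; bars are 95% intervals from Poisson redraws. Cholesterol synthesis in mature cells lies at 0.05 (red) and 0.25 (blue), interferon genes in cDC1-like cells at -0.59 and 0.22, and NF-kB genes in macrophage-like cells at 1.01 and -0.07.

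In cDC1-like cells of the Axl knockout library, interferon genes were lower and NF-kB genes higher than in wild type. The interferon list had a median of -0.59 [-0.65, -0.45] with 0 members higher and 19 lower. The antiviral gene Rsad2 stood at 3.73 against 16.6 CPM (-2.16 [-2.80, -1.55]), the interferon regulator Irf7 at 34.3 against 72.0 (-1.07 [-1.30, -0.85]) and Cxcl9 at 80.2 against 159.8 (-0.99 [-1.14, -0.85]). NF-kB genes gave 0.64 [0.49, 0.70] (12 higher, 1 lower), led by the chemokine Ccl4 at 167 against 38.2 CPM. Dissociation and stress genes gave 0.57 [0.45, 0.69] (9 higher, 5 lower), with the phosphatase Dusp1 at 510 against 147 CPM (1.79 [1.69, 1.90]) and the heat shock gene Hspa1a lower at -1.31 [-1.58, -1.04].

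With free RNA subtracted the NF-kB median was 0.22, with 4 of 13 members at 0 in both libraries, and with classes from each cell's own score it was 0.20. Hypoxia and glycolysis genes had Gapdh at 286 against 440.7 CPM (-0.62 [-0.71, -0.54]) in a list of median -0.17 [-0.22, -0.08] with 3 higher and 9 lower. MHC class I presentation gave -0.11 [-0.14, -0.04]. Cholesterol synthesis gave 0.00 and efflux -0.01, and immunogenic maturation genes gave a median close to these, at 0.04. Lipid-associated macrophage genes gave -0.54 [-0.64, -0.41] (1 higher, 10 lower) and macrophage markers -0.77 [-0.93, -0.65] (0 higher, 9 lower). Apoe stood at 29.2 against 129.7 CPM, which was 1.82% of its level in free RNA in this library and 1.33% in wild type. By the rule Ccl4, Dusp1, Cxcl2 (1.498), Ddit4 (1.44) and Ier2 (1.19) were highest and Apoe (-2.15), the protease Ctsd (-1.79), Hspa1a, Irf7 and Cxcl9 lowest. All but Irf7 were held by free RNA at 0.5 times their class share or more.

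In cDC1-like cells of the Zbtb46-Cre Axl-flox library, interferon genes were higher than in wild type, with a median of 0.22 [0.09, 0.29] (13 higher, 7 lower). Ifit1, which binds viral RNA, was at 1.20 [0.51, 1.91] and Oasl2 at 0.80 [0.48, 1.13], whereas Cxcl9 was at -0.38 [-0.55, -0.21]. With cells weighted equally the median was 0.03. The efflux, storage and export list gave 0.18 [0.07, 0.25] (13 higher, 3 lower), 0.08 at its lowest among the alternatives. Its member Scd2, a desaturase, was at 0.60 [0.43, 0.78]. Cholesterol synthesis gave -0.02, immunoregulation 0.17 and NF-kB genes 0.23 [0.09, 0.34]. Highest by the rule were the receptor Fgfr1 (1.19), Cdh17 (1.08), Arrdc4 (0.96), Txnip (0.95) and Ccl17 at 2297 against 1266 CPM. Lowest were the AP-1 genes Fosb (-1.30) and Jun (-0.996), Egr1 (-0.75), Ndufa3 (-0.71) and Atp5k (-0.69). Free RNA held less than 0.5 times the class share of Fgfr1 alone. Directly between the deletions, the interferon median was 0.63 [0.54, 0.73] (20 higher, 0 lower) in Zbtb46-Cre Axl-flox over Axl knockout, and dissociation and stress genes gave -0.72 (4 higher, 10 lower). Named genes of that pair were Apoe (2.28), Hspa1a (1.38), Hspa1b (1.26), Isg15 (1.21) and Lars2 (1.10), and in the other direction Fosb (-1.95), Fos (-1.76), Egr1 (-1.65), Ccl4 (-1.62) and Dusp1 (-1.56); free RNA held less than 0.5 times the class share of Isg15 alone.

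The cDC2-like cells of the Axl knockout library had higher Ch25h and Tnf, lower Abcg1 and Abca1, and lower medians of glycolysis and cell cycle genes than wild type. Ch25h stood at 52.3 against 8.49 CPM (2.62 [2.35, 2.91]), and its level in free RNA differed alike, at 55.8 against 6.17 CPM, while the cytokine Tnf stood at 82.7 against 33.0 (1.33 [1.18, 1.48]). The cholesterol exporters Abcg1 and Abca1 gave -1.03 [-1.23, -0.84] and -0.97 [-1.41, -0.52]. Gapdh stood at 349.5 against 516 CPM (-0.56 [-0.61, -0.52]) in a hypoxia and glycolysis list of median -0.26 [-0.30, -0.20] (2 higher, 11 lower). Cell cycle genes gave -0.39 [-0.45, -0.34] (0 higher, 15 lower), with Top2a at -0.78 [-0.87, -0.70]. That median was -0.04 with clusters weighted as in wild type: cycling cells formed 7.91% of the class here and 11.9% in wild type.

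Cholesterol synthesis and uptake gave 0.09 [0.06, 0.14] (20 higher, 3 lower). Efflux, storage and export gave -0.12 [-0.17, -0.07] (4 higher, 14 lower), and 0.00 with free RNA subtracted. Apoe was at 58.2 against 140.1 CPM (-1.27 [-1.36, -1.17]), and macrophage markers in the class gave -0.41 [-0.48, -0.35] (1 higher, 9 lower). Interferon genes gave -0.16 [-0.20, -0.10] (4 higher, 16 lower), and -0.55 with the clusters between classes joined, one of which was led by interferon genes. NF-kB genes gave 0.24 [0.21, 0.33] (10 higher, 3 lower), and 0.12 with clusters weighted as in wild type; dissociation and stress genes gave 0.18 (8 higher, 6 lower), and 0.06 with that weighting. By the rule Ch25h, Tnf, Fkbp5 (1.08), Pdcd4 (0.95) and Egr3 (0.88) were highest and Axl, Lyz2 (-1.49), Apoe, the fatty acid binding protein Fabp5 (-1.11) and Ifi27l2a lowest. In free RNA Lyz2 stood at 1297 CPM in Axl knockout and 8732 in wild type, and Apoe at 1609 and 9758.5. The lower Lyz2 and Apoe thus need not lie in the cDC2-like cells themselves.

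In the Zbtb46-Cre Axl-flox library the cDC2-like cells had higher cholesterol synthesis genes and lower interferon genes than wild type, and higher Ch25h. The synthesis list gave 0.26 [0.19, 0.30], 0.20 relative to all genes, with 21 higher and 2 lower, and 0.20 at its lowest among the alternatives. Its members Hsd17b7 (0.96 [0.55, 1.38]), Msmo1 (0.61 [0.44, 0.79]) and Hmgcs1 (0.54 [0.39, 0.70]) encode enzymes of the pathway. Ch25h stood at 32.4 against 8.49 CPM (1.93 [1.63, 2.24]). Interferon genes gave -0.27 [-0.33, -0.20] (2 higher, 17 lower), with Ifit3 at -1.49 [-2.11, -0.90] and Irf7 at -1.23 [-1.82, -0.65], and the median was -0.34 with the clusters between classes joined. Apoe was level at -0.01 [-0.10, 0.08] and Abca1 at -0.03 [-0.48, 0.43].

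Glycolysis genes gave 0.13, with Gapdh at 674 against 516 CPM (0.39 [0.34, 0.43]), and NF-kB genes gave 0.19 [0.10, 0.23], which was 0.05 with clusters weighted as in wild type. Cell cycle genes gave -0.14 [-0.24, -0.09] and turned to 0.16 with that weighting. Highest by the rule were the endotoxin receptor Cd14 (1.24), Lars2 (1.15), Enah (1.03), Gsr (0.95) and Klhl6 (0.86); lowest were Plac8 (-1.35), a leading gene of a cluster that held 6.33% of the class here and 14.8% in wild type, Axl (-1.17), Tnni2 (-0.91), Atp5k (-0.86) and the replication factor Pclaf (-0.80). With 10 CPM added Pclaf gave -0.72, and -0.34 with clusters weighted as in wild type. Enah and Pclaf alone had less than 0.5 times their class share in free RNA. Between the deletions TMM scaling moved ratios by -0.11. Zbtb46-Cre Axl-flox had higher hypoxia and glycolysis genes (0.28, or 0.22 relative to all genes; 12 higher, 1 lower), with Gapdh at 0.95 [0.91, 0.99], and efflux genes at 0.17 (0.11 relative; 0.09 with free RNA subtracted), with Abca1 at 0.94 [0.49, 1.39]; lipid-associated macrophage genes gave 0.30 (0.24 relative; 11 higher, 1 lower). With free RNA subtracted, which removes too much here, the lipid-associated median was 0, with 6 of 12 members at 0 in both libraries. In free RNA Apoe stood at 7797 CPM in Zbtb46-Cre Axl-flox and 1609 in Axl knockout. Named genes were Axl (2.74), Apoe (1.26), Lyz2 (1.19), Capg (1.18) and Gapdh, and in the other direction Egr3 (-1.44), Tnf (-1.09), Ccl4 (-1.02), Egr1 (-0.9996) and Ppp1r15a (-0.82).

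Macrophage-like cells of the Axl knockout library had higher inflammatory cytokine genes and lower lipid-associated macrophage genes than wild type. Tnf stood at 243 against 82.7 CPM (1.56 [1.46, 1.65]), Il6 was at 1.60 [1.28, 1.91] and the neutrophil chemokine Cxcl2 stood at 1431 against 507.5 CPM (1.496 [1.46, 1.54]). Spp1, encoding osteopontin, stood at 443 against 1385 CPM (-1.65 [-1.70, -1.59]), and the lipid receptor Trem2 was at -0.91 [-0.98, -0.84]. NF-kB genes gave a median of 1.01 [0.94, 1.09], 0.99 relative to all genes, with 14 higher and 0 lower, and lipid-associated genes -0.88 [-0.92, -0.84], -0.90 relative, with 0 higher and 12 lower. Dissociation and stress genes were higher in the same cells, at a median of 0.50 [0.40, 0.55] with 13 higher and 1 lower, and at 0.32 with clusters weighted as in wild type.

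TMM scaling moved ratios of this comparison by -0.10, and cluster sizes within the class differed. A cluster led by Ccr2, Cx3cr1 and C1qa, with a marker score of 0.52 for macrophages and 0.37 for cDC2, held 46.9% of macrophage-like cells in Axl knockout and 27.9% in wild type, while one led by Apoe, Lyz2 and Trem2 held 10.5% and 24.1% and one led by Il1a and Tnf 16.1% and 13.6%. Spp1, Trem2, Gpnmb and Cd63 of the lipid-associated list also served as markers of the class. With clusters weighted as in wild type the NF-kB median was 0.60 and the lipid-associated median -0.42. Cholesterol synthesis and uptake gave 0.22 [0.15, 0.28] (0.20 relative; 21 higher, 2 lower), with Idi1 at 0.74 [0.51, 0.97]. Efflux, storage and export gave -0.32 [-0.41, -0.25] (-0.34 relative; 4 higher, 14 lower), with Abcg1 at -0.75 [-0.88, -0.61], and -0.10 under that weighting. MHC class II genes gave 0.35 [0.34, 0.39] (0.33 relative; 10 higher, 1 lower), which was -0.00 under it. Interferon genes gave -0.17 [-0.24, -0.11] (-0.19 relative; 3 higher, 17 lower). TAM receptor and efferocytosis genes, Axl included, gave -0.18 (-0.20 relative; 4 higher, 13 lower). By the rule Tnf, Cxcl2 and Ccl4 (1.40) were highest and Axl, Fabp4 (-1.79) and Spp1 lowest; free RNA held less than 0.5 times the class share of Cxcl2 alone.

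The macrophage-like cells of Zbtb46-Cre Axl-flox lay nearer to wild type, with more Arg1, which breaks down arginine (405 against 198 CPM, 1.03 [0.98, 1.08]), and less Spp1 (-0.73 [-0.75, -0.71]). Cholesterol synthesis and uptake gave 0.17 [0.12, 0.19] (22 higher, 1 lower), with the pathway regulator Insig1 at 0.43 [0.27, 0.59]. Abcg1 was at -0.34 [-0.40, -0.27], interferon genes gave, close to the Axl knockout value, -0.16 [-0.22, -0.13] (1 higher, 19 lower), NF-kB genes -0.07 [-0.13, -0.03] and lipid-associated genes -0.17 (2 higher, 10 lower; -0.08 with clusters weighted as in wild type). By the rule Arg1, Chil3 (0.93) and Hopx (0.83) were highest and the chemokine Ccl5 (-0.97), Ifitm1 (-0.80) and Spp1 lowest. Between the deletions Axl (2.39), Fabp4 (1.72) and Arg1 (1.33) were highest in Zbtb46-Cre Axl-flox and Ifitm1 (-2.03), Ccl5 (-1.95) and Cxcl2 lowest, again with Cxcl2 alone below 0.5 times its class share in free RNA.

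List medians are of CPM with 10 added, which draws the ratios of weakly expressed members toward 0. Without the added 10, among other changes, the interferon median against wild type was -0.99 (Axl knockout) and 0.32 (Zbtb46-Cre Axl-flox) in cDC1-like cells, -0.44 and -0.71 in cDC2-like cells and -0.46 and -0.40 in macrophage-like cells, and between the deletions 1.13 in cDC1-like and 0.43 in mature cells. Cholesterol synthesis in mature cells was 0.11 and 0.41 against wild type and 0.28 between the deletions, and in cDC2-like cells 0.15 and 0.41. Efflux genes in mature cells of Zbtb46-Cre Axl-flox were at 0.22 over wild type and 0.37 over Axl knockout, and immunogenic maturation genes there at 0.35 over wild type, as in Axl knockout (0.35). In Axl knockout over wild type, NF-kB genes were at 0.94 in cDC1-like, 0.40 in cDC2-like and 0.60 in mature cells, lipid-associated genes at -0.89 in cDC1-like cells and cholesterol synthesis at 0.35 in macrophage-like cells.

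Both deletions were compared with the same wild type library, which alone makes their ratios correlate. Across 2047 genes of the mature class, which are not independent replicates, the log2 ratios of the deletions had a Pearson correlation of 0.52, against 0.46 in 100 simulations of unchanged groups. Their covariance was 0.0278, against a simulated 0.00622. In the cDC1-like class (2184 genes) the correlation was 0.54 against 0.48 and the covariance 0.0196 against 0.00294; in the cDC2-like class (2282 genes) 0.54 against 0.58 and 0.0167 against 0.00124. In macrophage-like cells (2378 genes) these values were 0.29 against 0.31 and 0.0105 against 0.000603. In these cells and cDC2-like cells the correlation was thus no higher than the simulated one, although the covariance was. The correlation was also below the simulated one in monocyte-like (0.37 against 0.66) and neutrophil-like cells (0.60 against 0.73). The simulations held counting error only, so a correlation no higher than theirs does not show that nothing was shared. The differences in covariance, of 0.0216, 0.0166, 0.0154 and 0.00993 in the order mature, cDC1-like, cDC2-like and macrophage-like, and 0.0271 and -0.0119 in monocyte-like and neutrophil-like cells, estimate what the deletions shared relative to this wild type library, which includes anything that set that library apart from both. With 1 wild type library it could not be split, so part of these differences may come from the shared control.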

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

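The test of the loss of Axl as the reason for the low interferon genes in cDC1-like cells was chosen only after its result was seen. The joining of the clusters between classes was added after the data were seen.

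The results below stand out because the same comparison gave opposite directions in different dendritic cell classes; with 1 library per genotype, none of these differences between classes was tested. In Axl knockout over wild type, MHC class I presentation genes had a median log2 ratio of -0.11 in cDC1-like and -0.11 in cDC2-like cells but 0.12 in mature cells, where it fell to 0.020 under TMM scaling and 0.0023 with classes from each cell's own score. In Zbtb46-Cre Axl-flox over wild type, type I interferon genes had a median of 0.22 in cDC1-like cells, or 0.032 with cells weighted equally, and -0.27 in cDC2-like cells. In the same comparison MHC class II presentation genes had a median of 0.12 in cDC1-like and 0.040 in cDC2-like cells but -0.20 in mature cells. Under TMM scaling the value in cDC1-like cells fell to 0.029 and that in cDC2-like cells turned to -0.049, and at a minimum of 1000 UMIs that in mature cells was -0.018.

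Interferon genes were lower in cDC1-like cells of the Axl knockout library, at a median of -0.59 with 0 of 19 members higher. A few cells with a strong interferon response in wild type would leave little difference once removed, but without the 10% of cells with the highest interferon score in each library the median was still -0.40. Cells were scored on the same genes and only this 10% was removed, so a larger group of interferon-high cells stays open. Interferon transcripts outside cells would lose weight when free RNA is subtracted, yet the median was then -0.61. Whether the loss of Axl in these cells lowered the genes stays open: in Zbtb46-Cre Axl-flox the median was 0.22, but Axl there was reduced by far less, with a log2 ratio of -0.71. The list median of Axl knockout over wild type was also below 0 in cDC2-like (-0.16), mature (-0.18) and macrophage-like cells. Its direction was thus not particular to cDC1-like cells. With the clusters between classes joined, the cDC2-like value was lower still. A difference between animals, sorts or lanes also stays open and was not tested, so a lower interferon response of Axl knockout cDC1-like cells may be considered only as a hypothesis.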

How the results depend on the processing

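The removal of the highest 6% of Scrublet scores, the joining of clusters between classes, the weighting of clusters as in wild type and list medians without the added 10 CPM were chosen after the data were seen. No paired analysis was possible because each genotype has 1 library, and no alternative left out a replicate. In the mature class all 10 leading list medians stayed within their counting intervals under 10 of the 13 alternatives run on them, the exceptions being TMM scaling (9 of 10), a minimum of 100 counts (9 of 10) and classes from each cell's own score (6 of 10). The 8 Axl ratios against wild type in the dendritic cell and macrophage-like classes kept their sign throughout, and 1 left its interval: in cDC2-like cells of Zbtb46-Cre Axl-flox -1.17 became -0.96 with classes from each cell's own score. In the mature class 10 of the 22 cholesterol synthesis members measured in Zbtb46-Cre Axl-flox over wild type had at least 100 counts. Without the added 10 CPM 55 of the 194 other list medians left their counting intervals and 0 turned sign among those whose interval lay off 0. Causes of the changes listed were not tested, except where the construction of an alternative shows one.

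Shares of cells are given in the order Zbtb46-Cre Axl-flox, Axl knockout, wild type unless a library is named. At a minimum of 1000 UMIs cDC2-like cells held 54.5% (Axl knockout) and 27.4% (wild type), mature cells 5.64%, 9.05% and 7.31%, and macrophage-like cells 48.7%, 9.77% and 42.0%. At a maximum of 10% mitochondrial UMIs cDC2-like cells held 32.2%, 57.3% and 30.8%, mature cells 6.87% (wild type) and macrophage-like cells 44.6%, 7.48% and 38.3%. With the 1 Scrublet call kept, cDC2-like cells held 29.1%, 54.1% and 28.7%, mature cells 3.79%, 6.84% and 5.23%, and macrophage-like cells 44.4% (Zbtb46-Cre Axl-flox) and 38.0% (wild type); 1 cell more changed the clusters. At Leiden resolution 1.5 with 30 components cDC1-like cells held 5.38% (Zbtb46-Cre Axl-flox), cDC2-like cells 28.4% (Zbtb46-Cre Axl-flox) and 26.8% (wild type), and mature cells 5.27% (Zbtb46-Cre Axl-flox) and 8.49% (Axl knockout). With classes from each cell's own score cDC1-like cells held 8.68%, 19.8% and 14.3%, cDC2-like cells 32.4%, 48.5% and 27.2%, mature cells 7.52%, 12.3% and 9.83%, and macrophage-like cells 9.54% (Axl knockout) and 43.9% (wild type). Without the highest 6% of Scrublet scores cDC2-like cells held 31.9%, 56.4% and 30.5%, mature cells 5.75%, 9.26% and 7.58%, and macrophage-like cells 44.1% (Zbtb46-Cre Axl-flox) and 7.99% (Axl knockout). With the clusters between classes joined, cDC2-like cells held 31.2%, 57.4% and 31.6%, by construction above the planned shares.

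Of the leading medians in mature cells, cholesterol synthesis in Zbtb46-Cre Axl-flox over wild type went from 0.25 to 0.61 over members with at least 100 counts, and immunoregulation there from 0.21 to 0.089 under TMM scaling and 0.10 with each cell's own score. With each cell's own score, medians in Axl knockout over wild type went from -0.07 to -0.22 (cholesterol efflux), from 0.11 to -0.046 (immunoregulation) and from -0.18 to -0.34 (interferon).

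Other medians changed sign. TMM scaling gave -0.049 for MHC class II in cDC2-like cells of Zbtb46-Cre Axl-flox over wild type, and between the deletions -0.072 for MHC class I and -0.077 for MHC class II in cDC2-like cells and -0.00034 for migration in mature cells, which was -0.023 with cells weighted equally. MHC class II in mature cells between the deletions was -0.034 with the Scrublet call kept and -0.12 with each cell's own score. Own scores also gave, in Axl knockout over wild type, -0.0018 for immunoregulation in cDC1-like cells, 0.065 for naive and central memory T cell genes in cDC2-like cells and -0.069 for T cell checkpoint genes in mature cells, and between the deletions 0.031 for interferon and -0.018 for MHC class II genes in cDC2-like cells. Subtraction of free RNA, which removes too much from dendritic cell classes, gave 0.0026 for cholesterol efflux in cDC2-like cells of Axl knockout over wild type and 0.0026 for migration in macrophage-like cells between the deletions. Joining the clusters between classes gave -0.075 for lipid-associated macrophage genes in cDC2-like cells of Zbtb46-Cre Axl-flox over wild type and 0.25 for interferon genes in these cells between the deletions, where an interferon-led cluster was added. Weighting clusters as in wild type, which removes differences in cluster sizes, gave 0.055 for cell cycle genes in cDC1-like and 0.16 in cDC2-like cells of Zbtb46-Cre Axl-flox over wild type, -0.049 for lipid-associated macrophage genes in the latter, and 0.0033 for cell cycle genes in cDC1-like cells between the deletions. In macrophage-like cells it gave -0.00070 for MHC class II and -0.11 for cell cycle genes in Axl knockout over wild type, and 0.10 for the IL-4 response and 0.11 for cell cycle genes between the deletions.

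Among named genes (log2 ratio with 10 CPM added) signs turned mostly in the smallest classes. In monocyte-like cells own scores gave Mmp9 0.85 in Axl knockout and, in Zbtb46-Cre Axl-flox over wild type, Mmp9 0.12, Tppp3 -0.0072 and Adamdec1 0.31; there a minimum of 1000 UMIs gave Mmp13 0.11 and Adamdec1 0.30, and Axl was 0.44 with the Scrublet call kept. In neutrophil-like cells Fabp5 in Zbtb46-Cre Axl-flox over wild type was 0.10 at a minimum of 1000 UMIs, 0.078 with the Scrublet call kept and 0.19 without the highest 6% of Scrublet scores, which also gave Cxcl9 -0.47 and C1qb -0.48 between the deletions. In mature cells Lyz2 between the deletions was -0.090 at a maximum of 10% mitochondrial UMIs.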

Other observations

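The tests of Axl loss in dendritic cells alone, of free RNA as the source of the remaining Axl and of lipid-associated genes in cells with high Scrublet scores were chosen only after their results were seen, and the removal of the highest 6% of Scrublet scores and the weighting of clusters as in wild type were alternatives added after the data were seen.

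Monocyte-like cells were few, with 146, 214 and 91 cells in Zbtb46-Cre Axl-flox, Axl knockout and wild type (2.33%, 2.97% and 1.35% of cells). Their cluster scored 0.58 for classical monocytes and 0.55 for macrophages. In wild type it held C1qa at 2258 CPM, against 1339 in macrophage-like cells, and S100a8 at 92.0. In Axl knockout C1qa stood at 644 and S100a8 at 2372 CPM. The libraries thus seem to hold different mixes of cells under this name, and ratios in the class need not be changes within monocytes. In the Axl knockout library hypoxia and glycolysis genes of the class were far lower than in wild type, with a median log2 ratio of -1.23 [-1.42, -1.16] and 13 of 13 members lower. Vegfa, an angiogenic growth factor, was at -1.96 and Gapdh at -1.46. Lipid-associated macrophage genes gave -1.003 (0 higher, 12 lower), while immunogenic maturation genes gave 0.58 (10 higher, 0 lower). Markers of other cells moved with them: interstitial or monocyte-derived macrophage markers gave -1.42 (0 higher, 10 lower), with C1qa at 644 against 2258 CPM, classical monocyte markers 1.61 (8 higher, 0 lower) and neutrophil markers 2.75 (5 higher, 1 lower). In Zbtb46-Cre Axl-flox the first of these medians was 0.05 and cell cycle genes were higher, at 0.46 [0.34, 0.65] with 15 of 15 members higher. The class of the Axl knockout library also held neutrophil granule transcripts, with Camp at 567 CPM and 0 counts in wild type, S100a9 at 6.33 and Lcn2 at 5.80. Its lowest genes by the rule were Mmp13 (-4.52), Axl (-3.97) and Mmp9 (-3.37), of which Mmp9 turned to 0.85, with 10 CPM added, with classes from each cell's own score. In Zbtb46-Cre Axl-flox over wild type Tppp3 (2.93), Lcn2 (2.76) and Prg4 (2.16) were highest and Mmp9 (-7.48), Mmp13 (-2.72) and Adamdec1 lowest, but with 10 CPM added own scores gave Tppp3 -0.0072, Mmp9 0.12 and Adamdec1 0.31, and a minimum of 1000 UMIs gave Mmp13 0.11. Between the deletions Axl (3.30), Slc7a2 (2.43) and Spp1 (2.12) were highest in Zbtb46-Cre Axl-flox and S100a9 (-9.01), Camp and Ngp (0 against 567 and 233 CPM) lowest. Of the genes the rule named in this class, free RNA held Axl alone at 0.5 times its class share or more.

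Neutrophil-like cells numbered 68, 156 and 52 and were shallow, with medians of 1502.5, 1412.5 and 1236 UMIs. MHC class II genes were higher in both deletions, at 0.89 and 1.07 (10 of 10 members each), although neutrophils make little of these proteins; Cd74 was at 0.82 and 1.16. Both ratios share the 52 wild type cells. Among macrophage genes in this class, C1qb stood at 384, 91.9 and 77.3 CPM in Zbtb46-Cre Axl-flox, Axl knockout and wild type, whereas Apoe stood at 576, 410 and 754. TMM scaling moved ratios by 0.31 in Axl knockout over wild type and by -0.30 between the deletions. The granule genes Camp (746 CPM against 0), Ltf (249.5 against 0) and Ngp (5.60), made by immature neutrophils, were highest in Axl knockout over wild type, and Fabp5 (-2.34), Basp1 (-1.77) and Timm10b (-1.62) were lowest. In Zbtb46-Cre Axl-flox over wild type Cxcl9 (6.35), Mgl2 (3.27) and Ap1s2 (2.42) were highest and Gngt2 (-1.44), Tnfaip2 (-1.34) and Fabp5 (-1.28) lowest, and over Axl knockout Cxcl9 (8.23), Lgmn (2.23) and C1qb (2.06) were highest and Camp (-7.17), Ltf (-5.59) and Ngp (-3.56) lowest. With 10 CPM added and without the highest 6% of Scrublet scores, Cxcl9 turned to -0.47 and C1qb to -0.48 between the deletions and Fabp5 to 0.19 over wild type, where it also turned at a minimum of 1000 UMIs (0.10) and with the Scrublet call kept (0.078). Free RNA held Fabp5, Timm10b, Mgl2, Ap1s2, Gngt2, Lgmn and C1qb at 0.5 times their class share or more. Plasmacytoid dendritic cell-like cells numbered 0, 9 and 1; 0 of 6279 cells allows a share of up to 0.0478% (3 cells of the total). Haemoglobin and other erythroid transcripts in macrophage-like cells were lower in both deletions, at -1.27 and -1.28, with 0 of 4 markers higher. These transcripts were weak, with 0 of 6 erythroid markers reaching the detection level in any cluster. Both ratios share the wild type library, so a difference of that library alone cannot be told apart from the deletions. Lists of T cell genes had few measured members. T and NK cytotoxicity genes gave no median in any class, for want of 3 measured members. In mature cells the checkpoint list gave 0.25 in Axl knockout and 0.12 in Zbtb46-Cre Axl-flox over wild type, and the naive and central memory list 0.19 and -0.10. In mature cells the hypoxia list gave -0.06 and 0.18, the cell cycle list 0.14 and 0.15, dissociation genes -0.06 and 0.09, and TAM receptor genes 0.09 and 0.19. Mixed clusters, which joined macrophage genes with those of cDC1 or mature dendritic cells, had medians of 15519, 13376 and 15643.5 UMIs per cell, above those of their libraries.

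Axl was lower in macrophage-like cells of the Zbtb46-Cre Axl-flox library as well, at a log2 ratio of -0.69. This was close to the ratios in cDC1-like (-0.71) and mature cells (-0.70). A shift between macrophage-like clusters would leave the levels within clusters close to wild type, yet the mean ratio within clusters was -0.73. Loss in dendritic cells alone would leave macrophages at 0; the upper counting bound of their ratio was -0.63, but with 1 library each, such loss and a difference between the libraries cannot be told apart. Axl that remained in cDC2-like cells of this library was too abundant for macrophage RNA from outside the cells as its main source: Apoe stood there at 1.79% of its level in free RNA and C1qa, C1qb and C1qc at 7.20%, 7.20% and 6.20%, against 42.5% for Axl. Cre activity in other cells or a floxed allele of lower expression could each lower Axl in macrophages; neither was tested, and the labels give no floxed library without Cre.

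Lipid-associated macrophage genes were lower in cDC1-like cells of the Axl knockout library, with a median of -0.54, and this library also held the fewest macrophage-like cells, at 8.70%. Doublets with macrophages cannot be told apart as a source. The highest 6% of Scrublet scores took 86 of 900 cells of the class in Axl knockout and 32 of 629 in wild type. Without them the median was -0.55 with classes kept and -0.59 with the remaining cells clustered again. These scores took 236 of 472 mixed cells in wild type, but by the list's median they marked macrophage RNA only weakly within the class. In high-score cells over the others this median was 0.14 in wild type, 0.27 in Axl knockout and 0.27 in Zbtb46-Cre Axl-flox. In summed counts the ratios were 0.52 [0.43, 0.61], 0.30 [0.23, 0.37] and 1.01 [0.88, 1.14] in that order. If all Gpnmb, which macrophages express, came from free RNA, its share of cDC1-like counts was 1.09% in Axl knockout and 1.13% in wild type. With free RNA subtracted at these shares the median of the other 10 members went from -0.49 to -0.19. Doublets with macrophages carry Gpnmb too, so this subtraction also removes their RNA. Values below 0 were set to 0, and a member at 0 in both libraries has a ratio of 0 whatever the cause. Part of the move toward 0 may thus be built into the subtraction. Less macrophage RNA, outside cells or in doublets, may account for some of this pattern, but how much is left open. These sources cannot be told apart by this test, and no biological explanation was tested.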
